A study of Mus musculus with 9 samples.

How the data were processed

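The authors deposited 1 table of FPKM (fragments per kilobase of transcript per 1e6 mapped reads) for 54532 mouse genes in 9 libraries. Per the labels, the samples were choroidal and retinal flat mounts of C57BL/6 mice. RNA was extracted with Trizol, mRNA was selected with poly-T beads from 1 µg of RNA, and libraries were made with a NEBNext Ultra kit and sequenced on an Illumina instrument. The kit does not mark the strand, so overlapping genes on opposite strands cannot be told apart. Reads were assigned to genes of the mm10 build with HTSeq 0.6.0, per the submitters' processing notes. The aligner is not given in the sources used here.

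The deposited FPKM multiplied by the deposited gene length was a whole multiple of 1 step in each library, for 100% of values within a tolerance of 0.05, so read counts were recovered from it. The recovered totals were 16990118 to 18753737 reads per library. The steps showed that the deposited FPKM had already been scaled by the median of ratios, so a repeat with that scaling changed almost nothing and was set aside as void. Read counts of near-identical gene copies, such as Rps3a1 and Rps3a2, Tpm3 and Tpm3-rs7 or the gamma crystallins, are uncertain. Floors and the interval of the opposite-sign share cover counting error only. Intervals of differences between list medians came from 10000 resamplings of marker genes and leave out the spread between libraries.

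The choice of test, threshold, filter, gene lists, focus genes, named-gene rule and most alternatives was made before the data were examined. Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, 14086 in all. log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 9 libraries in the same fit and no covariate. Moderated statistics used the trend and robust options with statmod 1.5.0, p-values were two-sided, and they were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. A branch planned for a table of counts was not needed, as the table held FPKM. Exact tests on ranks of 3 against 3 libraries cannot go below p = 0.10, so none was used.

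A total of 35 gene lists fixed in advance, for cell types, tissues and processes of the eye, were tested with limma camera at a preset correlation between genes of 0.01, adjusted over the lists within each comparison. Every list had at least 3 tested members. Beside it, camera with a correlation estimated for each list was run, and called 1, 0 and 0 lists in the 3 comparisons, against 18, 19 and 14 with the preset correlation. Members of a list were also adjusted over that list alone.

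Named genes followed a fixed rule. For each comparison they were the 10 largest rises and the 10 largest falls on the log2 scale among called genes whose groups did not overlap in any library, leaving out symbols of the Gm number and Rik types. By chance alone, 10% of genes would not overlap in 3 against 3 libraries. Up to 4 members with the smallest p from each discussed list and 17 focus genes chosen beforehand were added. The text draws on these, with the most abundant genes beside them, and some named genes are not reported here. Where a group was 0 in every library, a floor of 3 reads per library gave the lowest fold change that the depth allowed. Coordinates are those of the deposited table, and 98.3% of them were identical to GENCODE M21 (GRCm 38).

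Alternatives tried were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, a fit of only the 2 groups compared, a fit without trend and robust options, array weights, the replicate number as a block, each library left out in turn and fry in place of camera. Alternatives added after the data were examined were limma voom on the recovered reads, reads scaled to each library's own total, FPKM divided by its sum, and the mean of the lens list as a covariate. limma voom called 6457, 2352 and 4977 genes in the 3 comparisons, of which 6097, 1860 and 4605 were also called by the test on FPKM.

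The test was tested on simulated data made from the spread of the real libraries, with 100 genes changed at each of 2 sizes. Changes of 1 on the log2 scale were recovered for 94%, 90% and 94% of genes in the 3 comparisons, and changes of 0.5 for 51%, 45% and 47%. Unchanged genes made up 7.05%, 6.25% and 6.0% of the called ones. A shifted list was called in each comparison and 0 other lists were. The simulated genes were independent, so this does not test false list calls among correlated genes. limma voom was tested on simulated data with less noise than many real genes have, where it recovered 97% of 200 genes changed 2-fold, and 3.96% of the called genes were unchanged.

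The opposite-sign share was the share of genes called in CNV against untreated with the opposite sign in BetP-Gel@Ran against CNV. It was set beside 20 simulations with no effect in which both comparisons shared the CNV libraries. In each, as many genes as were really called were taken by largest statistic, so noise alone picked them. With 3 libraries per group the CNV libraries could not be split between both comparisons. The interval of the share was an exact Clopper-Pearson interval over genes, which are not independent. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw reads and transcript isoforms were not analysed here.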

Results

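RNA from choroidal and retinal flat mounts of C57BL/6 mice was sequenced in 3 groups of 3 libraries. The groups were untreated mice, mice labelled CNV, whose sample titles refer to the wet form of age-related macular degeneration, and mice labelled BetP-Gel@Ran. The BetP-Gel@Ran samples were taken 3 months after an intravitreal injection. No sampling time is given for the untreated and CNV samples, so time may differ between the groups and cannot be told apart from treatment. The series concerns a hydrogel given with ranibizumab, an antibody fragment that binds human vascular endothelial growth factor A (VEGF-A). Its binding to the mouse protein is not covered by these data. The comparisons therefore address how CNV samples differed from untreated ones, and how samples after the injection differed from both. The labels do not say whether the BetP-Gel@Ran mice had CNV, and their treatment field names the gel without ranibizumab. Nothing in the labels says that the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Reads of libraries of the same group differed by more than counting error, with a chi-square per gene of 9.03 to 48.9 over pairs. These values argue against repeat sequencing of the same library. They do not show separate animals. Values are FPKM, given as mean ± SD (n = 3), and fold changes are on the log2(FPKM + 1) scale with their SE, which understates the change of low genes.

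The libraries held 16990118 to 18753737 reads on genes, and 13164 to 13481 genes reached 1 FPKM in each. Across genes, which are not independent replicates, log2 values of libraries of the same group correlated with r of 0.981 to 0.990. Untreated and CNV libraries correlated least, with r of 0.912 to 0.942. BetP-Gel@Ran libraries correlated with untreated ones at 0.953 to 0.962 and with CNV ones at 0.944 to 0.979. The first principal component held 58.6% of the variance and placed the BetP-Gel@Ran libraries between the other groups, and the second held 17.9%. The second set the BetP-Gel@Ran libraries apart from both, at -26.9 to -18.8 against 0.0159 to 20.3 in the other groups.

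**Figure D1:**
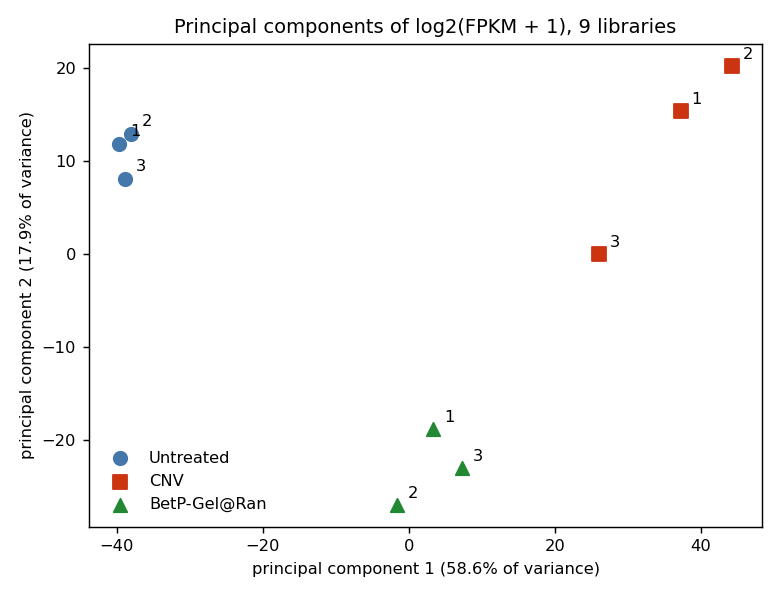
Principal components of log2(FPKM + 1) over the tested genes, with the first component (58.6% of the variance) against the second (17.9%) and 1 point per library. The BetP-Gel@Ran libraries lie between the untreated and CNV libraries on the first component and apart from both on the second.

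The libraries held transcripts of retina together with those of the front of the eye. The gene with the highest mean FPKM among nuclear genes was Gsto1, a glutathione transferase family member, at 10034 ± 895 FPKM in untreated, 11509 ± 1619 in CNV and 13239.8 ± 1158 in BetP-Gel@Ran libraries. The corneal keratin gene Krt12 reached 4677 ± 552 FPKM in untreated libraries, and Aldh3a1, the abundant aldehyde dehydrogenase of corneal epithelium, reached 6055 ± 528 FPKM. Genes of a fixed cornea and surface epithelium list took 4.39 ± 0.266% of reads in untreated, 2.63 ± 0.127% in CNV and 3.59 ± 0.321% in BetP-Gel@Ran libraries. Rod photoreceptor markers took 2.28 ± 0.256%, 1.01 ± 0.120% and 1.31 ± 0.203% of reads in the same order. Skeletal muscle genes took 1.11 ± 0.00475%, 0.222 ± 0.0650% and 0.274 ± 0.0295%. Lens genes varied most within a group, with 1.06 ± 1.57% of reads in untreated, 0.0298 ± 0.0117% in CNV and 0.552 ± 0.408% in BetP-Gel@Ran libraries. The spread among untreated libraries came from replicate 3, which held more lens reads than the other two.

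**Figure D2:**
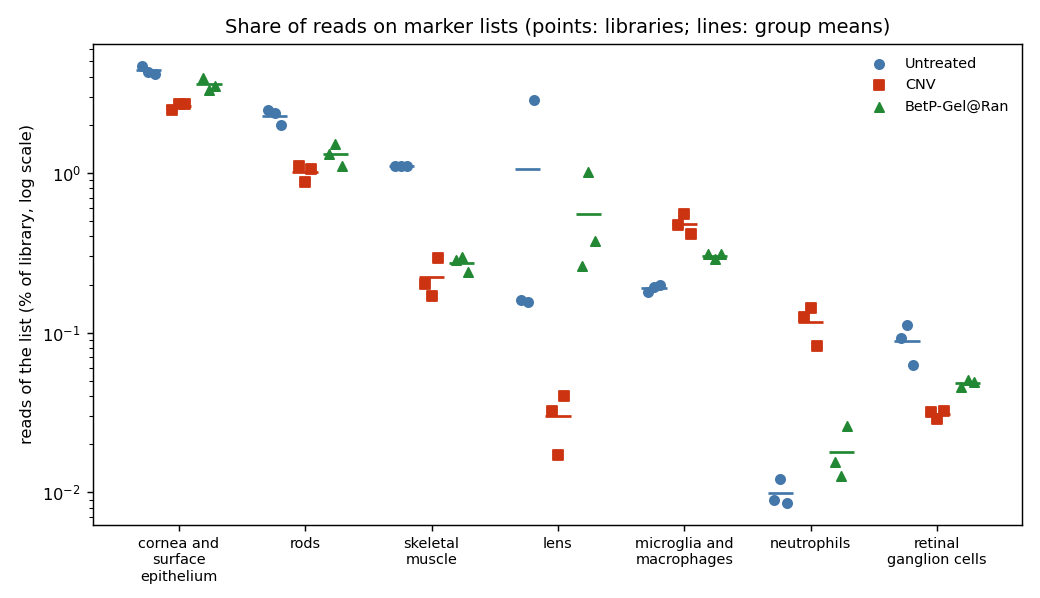
Percent of each library's reads on the genes of 7 fixed marker lists, on a log axis, with points for libraries and lines for group means. Muscle and rod shares were highest in the untreated libraries, and lens shares differed most between libraries of the same group.

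CNV samples differed from untreated ones in a large part of the transcriptome. As lists, genes of cytokines and chemokines, neutrophils, macrophages, complement and reactive gliosis were higher in CNV samples, and those of rods, retinal ganglion cells, skeletal muscle and the lens were lower. Of these lists, complement was also called with an estimated correlation (adjusted p = 0.0467), whereas the others had adjusted p = 0.192 to 0.504 with an estimated correlation. Of 14086 tested genes, 3166 were higher and 3115 lower in CNV samples (limma, Benjamini-Hochberg adjusted p under 0.05), and 545 and 601 of these changed by at least 1 on the log2 scale. Of the called genes, 50.4% were higher, which became 62.3% when reads were scaled to each library's own total. With 1 library left out at a time, the counts ranged from 2593 to 3127 higher and from 2513 to 3075 lower. They fell to 1126 and 1610 with the lens list as a covariate, and 1735 were higher with a filter of 5 FPKM.

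The largest rise was in Ppbp, which encodes a platelet chemokine that attracts neutrophils (ENSMUSG00000029372, mm10 chromosome 5, 90768518 to 90770063). It went from 1.99 ± 0.937 FPKM in untreated to 1335 ± 567 in CNV libraries, a log2 fold change of 8.75 ± 0.59 (limma adjusted p = 3.10e-05). Its chromosomal neighbour Cxcl5, another neutrophil chemokine gene, rose from 2.42 ± 0.459 to 80.3 ± 36.2 FPKM (limma adjusted p = 2.21e-05). Il1b, the gene of interleukin-1 beta (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), rose from 0.442 ± 0.0530 to 27.1 ± 8.94 FPKM, by 4.23 ± 0.35 on the log2 scale (limma adjusted p = 4.34e-05). Csf3, which drives neutrophil production, rose by 3.47 on the log2 scale, and Ccl2, a monocyte chemokine gene, by 2.74. Il33, an alarmin released by damaged cells, rose from 11.9 ± 0.344 to 52.6 ± 9.57 FPKM. Neutrophil genes followed: S100a8 rose from 3.76 ± 0.970 to 154 ± 62.7 FPKM, and Ltf, the lactoferrin of secretory granules and glands, from 12.3 ± 3.69 to 209 ± 52.5. Camp, another granule gene of neutrophils, was only at 2.69 to 3.20 FPKM in CNV and 1.49 to 1.79 in untreated libraries. The cells behind the rise of Ltf are therefore not known. Cxcr2, the receptor for Ppbp and Cxcl5, rose by 2.01, and Csf3r, the receptor for the product of Csf3, by 2.38. Spp1, the osteopontin gene, rose from 22.3 ± 2.21 to 509 ± 170.2 FPKM (log2 4.40 ± 0.41, limma adjusted p = 9.20e-05). Sprr2f, a gene of the cornified envelope of surface epithelium, rose from 1.20 ± 0.319 to 59.9 ± 33.2 FPKM, and Clec4d, a C-type lectin receptor gene of myeloid cells, from 0.292 ± 0.113 to 22.4 ± 8.34. Rps3a2 rose by 5.60, but it is a near-identical copy of Rps3a1, and reads cannot be assigned firmly between such copies.

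Of 28 tested cytokine and chemokine genes, 21 were higher and 2 lower (23 and 2 adjusted over the list alone), with a median log2 fold change of 1.77 (camera adjusted p = 9.27e-09, and adjusted p = 0.192 with an estimated correlation). Tnf was an exception at 11.1 ± 3.59 FPKM in untreated and 6.22 ± 1.87 in CNV libraries, with a lower value (limma adjusted p = 0.0224) that was not called without untreated replicate 1 (adjusted p = 0.0666), CNV replicate 1 (0.0767) or CNV replicate 2 (0.0791). All 24 called members of the 28 tested microglia and macrophage markers were higher (25 adjusted over the list alone), at a median of 1.53 (camera adjusted p = 1.58e-12, and adjusted p = 0.192 with an estimated correlation). Lyz2, the lysozyme gene of myeloid cells, rose from 222 ± 16.4 to 1157 ± 217 FPKM, and Ctss, a lysosomal protease gene, from 32.9 ± 1.60 to 185 ± 51.1. Csf1r, the receptor that maintains microglia and macrophages, rose from 5.44 ± 0.158 to 12.97 ± 0.387 FPKM, and the microglial marker Aif1 from 3.30 ± 0.924 to 12.5 ± 0.978. Of 9 neutrophil markers, 8 were higher, also when adjusted over the list alone, at a median of 2.38 (camera adjusted p = 1.07e-04, and adjusted p = 0.192 with an estimated correlation). Red blood cell genes took 0.329 ± 0.0708% of reads in untreated, 0.910 ± 0.580% in CNV and 0.572 ± 0.336% in BetP-Gel@Ran libraries, highest in CNV replicate 2. They were higher in 2 of 7 and in none adjusted over the list alone, and were not called as a list (median 1.20, camera adjusted p = 0.0992). Complement genes were higher in 15 and lower in 1 of 20 (16 and 1 adjusted over the list alone), at a median of 1.06 (camera adjusted p = 1.20e-06), and this call held with an estimated correlation (adjusted p = 0.0467). C3, the central complement component, rose from 2.51 ± 0.829 to 21.6 ± 5.14 FPKM (limma adjusted p = 3.16e-05), and Itgb2, the beta chain of complement receptors on leukocytes, by 2.43 on the log2 scale.

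Reactive gliosis genes had a median of 0.85, with 18 of 24 higher and 2 lower (19 and 2 adjusted over the list alone; camera adjusted p = 1.80e-06, and adjusted p = 0.192 with an estimated correlation). Serpina3n, a protease inhibitor of reactive astrocytes and Müller glia, rose from 7.65 ± 0.602 to 349 ± 179.8 FPKM (log2 5.22 ± 0.30, limma adjusted p = 1.00e-05). Gfap, the glial intermediate filament gene, rose from 14.5 ± 1.34 to 34.9 ± 11.9 FPKM (limma adjusted p = 0.00307), and Socs3, a feedback inhibitor of cytokine signalling, from 1.68 ± 0.151 to 17.8 ± 4.44. The water channel gene Aqp4 rose from 2.38 ± 0.286 to 23.4 ± 3.99 FPKM, while Glul, the glutamine synthetase of Müller glia, fell from 686 ± 42.0 to 300.1 ± 21.9. NF-kappa B and inflammasome genes had a median of 0.61, with 18 of 21 higher and 2 lower, the same counts adjusted over the list alone (camera adjusted p = 2.71e-06, and adjusted p = 0.192 with an estimated correlation). Ptgs2, the inducible cyclooxygenase gene, rose from 0.535 ± 0.0367 to 5.49 ± 1.92 FPKM. Cell cycle genes were higher in 18 of 24 (22 adjusted over the list alone), with Mki67, a marker of dividing cells, at 0.551 ± 0.0760 and 2.65 ± 0.991 FPKM (camera adjusted p = 1.80e-06, and adjusted p = 0.466 with an estimated correlation). Apoptosis and cell stress genes (median 0.39, camera adjusted p = 4.77e-04) and antigen presentation genes (median 0.45, camera adjusted p = 0.00101) were also higher as lists, each with adjusted p = 0.192 with an estimated correlation. Apoptosis genes had 16 of 28 higher and 1 lower, or 17 and 2 adjusted over the list alone. Antigen presentation genes had 10 of 19 higher, the same count adjusted over the list alone. Lymphocyte markers (camera adjusted p = 0.0198, and adjusted p = 0.192 with an estimated correlation) and immediate early genes (camera adjusted p = 0.00941, and adjusted p = 0.399 with an estimated correlation) were higher as lists, by medians of 0.78 and 0.41. They had 6 of 8 higher and 1 lower, and 10 of 19 higher and 1 lower, the same counts adjusted over the list alone. Hmox1, the inducible haem oxygenase gene, rose from 10.9 ± 2.70 to 71.9 ± 37.8 FPKM (limma adjusted p = 9.34e-04), although its oxidative stress list was not called.

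Rod and ganglion cell genes of the retina fell. Of 24 rod markers, 20 were lower and none higher (22 lower adjusted over the list alone), at a median of -1.11 (camera adjusted p = 3.12e-09, and adjusted p = 0.192 with an estimated correlation). The rod transcription factor genes Nrl and Nr2e3 fell to 82.7 ± 12.3 and 22.6 ± 3.27 FPKM, from 199.9 ± 15.0 and 59.0 ± 4.02 (limma adjusted p = 7.92e-05 and 4.34e-05). Of 16 retinal ganglion cell markers, 14 were lower, the same count adjusted over the list alone, at a median of -1.21 (camera adjusted p = 7.26e-08, and adjusted p = 0.192 with an estimated correlation). The neurofilament gene Nefl fell from 66.9 ± 19.8 to 12.04 ± 1.26 FPKM (limma adjusted p = 3.42e-05), and Nrn1, a neurite growth gene, from 17.8 ± 2.86 to 2.52 ± 0.813. Bipolar cell markers were lower in 2 of 10 and not called as a list (median 0.08, mean -0.07, camera adjusted p = 0.844). Cone markers were higher in 2 and lower in 3 of 12, the same counts adjusted over the list alone, and were not called as a list either (median -0.68, mean -0.34, camera adjusted p = 0.313). Of amacrine cell markers, 4 of 9 were lower and none higher, also when adjusted over the list alone, without a list call (median -0.14, mean -0.53, camera adjusted p = 0.0689). Of horizontal cell markers, 2 of 3 were lower, also when adjusted over the list alone, without a list call (median -1.48, camera adjusted p = 0.0611). Rpe65, the visual cycle isomerase gene of the pigment epithelium, did not differ detectably, at 79.3 ± 28.3 and 82.3 ± 20.9 FPKM (limma adjusted p = 0.830).

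Skeletal muscle and lens genes were lower as well. All 15 tested skeletal muscle genes were lower, also when adjusted over the list alone, at a median of -2.64 (camera adjusted p = 1.58e-12, and adjusted p = 0.192 with an estimated correlation). Acta1, the skeletal muscle actin gene, fell from 1558 ± 118 to 171 ± 54.3 FPKM (limma adjusted p = 8.06e-06). Lens genes had a median of -3.83, with 13 of 23 lower (15 adjusted over the list alone; camera adjusted p = 2.71e-06, and adjusted p = 0.504 with an estimated correlation). The largest fall among all called genes was in Cryge, a gamma crystallin gene (ENSMUSG00000070870, chromosome 1, 65048554 to 65051149), which went from 574 ± 692 FPKM to 0 in all 3 CNV libraries. Against a floor of 3 reads per library this was at least 2575-fold lower, and Crygf and Cryga were at least 708-fold and 216-fold lower. The untreated means were carried by replicate 3, and without it the 3 bounds were 789.7-fold, 216-fold and 45.7-fold. Crygb, Crygc, Crygd, Crybb1 and Crybb3 were lower in CNV libraries too. Cryge, Crygf and Cryga were also at or near 0 in the BetP-Gel@Ran libraries, so a strain or batch difference from the untreated mice is not excluded. Crygs (limma adjusted p = 0.0332) was not called without CNV replicate 1 (adjusted p = 0.0526), CNV replicate 2 (0.108) or CNV replicate 3 (0.05002), and the crystallin genes have near-identical copies. Oxidative phosphorylation genes were lower in 25 of 37 (27 adjusted over the list alone), at a median of -0.38 (camera adjusted p = 2.47e-08, and adjusted p = 0.192 with an estimated correlation). Glucocorticoid-induced genes (camera adjusted p = 0.0102, and adjusted p = 0.192 with an estimated correlation) and circadian clock genes (camera adjusted p = 0.0161, and adjusted p = 0.466 with an estimated correlation) were lower, by medians of -0.40 and -0.32. Glucocorticoid-induced genes had 4 of 24 higher and 12 lower, or 5 and 12 adjusted over the list alone, and clock genes had 2 of 19 higher and 9 lower, the same counts adjusted over the list alone. These calls were lost among genes of at least 5 FPKM, with adjusted p of 0.123 and 0.0578. Fkbp5, a glucocorticoid receptor cochaperone gene, fell from 14.8 ± 0.966 to 3.80 ± 0.541 FPKM, and Tsc22d3, a mediator of glucocorticoid action, from 65.7 ± 6.14 to 16.3 ± 3.87 (limma adjusted p = 1.02e-04 and 3.75e-05).

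Vessel and matrix genes were not called as lists. Vegfa, the mouse VEGF-A gene, rose from 6.13 ± 0.825 to 9.98 ± 2.25 FPKM (log2 0.61 ± 0.15, limma adjusted p = 0.00991). Its receptor genes Kdr and Flt1 and the endothelial marker Pecam1 were not called (limma adjusted p = 0.130, 0.627 and 0.804), at 1.38, 0.772 and 1.24 FPKM in CNV libraries. Esm1, a gene of sprouting endothelial cells, rose from 1.43 ± 0.271 to 4.07 ± 1.11 FPKM. Of 26 endothelial and angiogenesis genes, 7 were higher and 3 lower, or 7 and 3 adjusted over the list alone (median -0.02, mean 0.10, camera adjusted p = 0.590). Of 38 extracellular matrix genes, 12 were higher and 12 lower, or 12 and 12 adjusted over the list alone (median -0.04, mean 0.12, camera adjusted p = 0.868). Col1a1, a fibrillar collagen gene, fell from 123 ± 9.92 to 34.3 ± 12.7 FPKM (limma adjusted p = 1.79e-04). Interferon-stimulated genes (camera adjusted p = 0.248), hypoxia and glycolysis genes (0.401), Müller glia markers (0.907), pigment epithelium markers (0.313) and cornea genes (0.0992) were not called as lists.

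**Figure D3:**
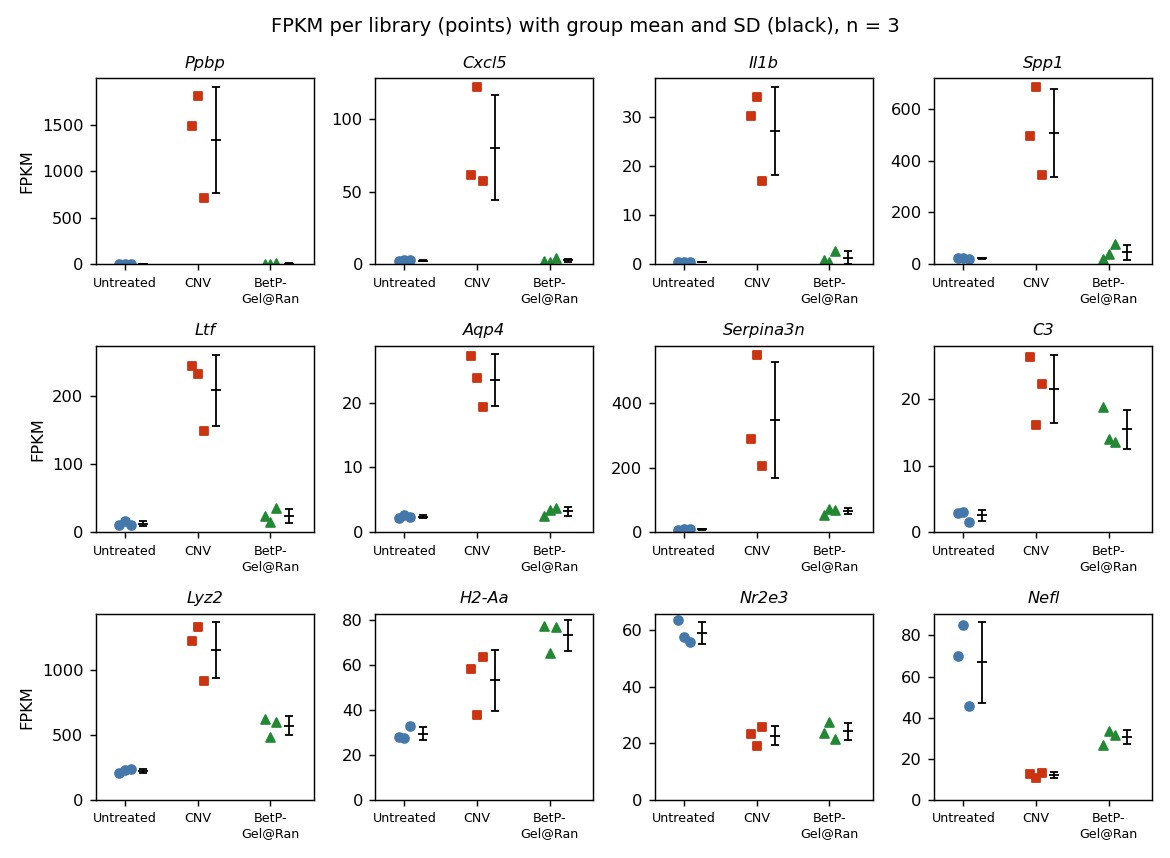
FPKM of 12 genes in each library, with group means and SD (n = 3). Il1b and Ppbp were high in the CNV libraries alone, whereas C3 and H2-Aa were above the untreated level in the BetP-Gel@Ran libraries.

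Samples after the BetP-Gel@Ran injection differed from CNV samples in fewer genes than CNV samples did from untreated ones. As lists, genes of cytokines and chemokines, neutrophils, macrophages and reactive gliosis were lower than in CNV samples, and those of retinal ganglion cells were higher. These list calls were lost with an estimated correlation, with adjusted p = 0.335 to 0.405 with an estimated correlation. Of 14086 tested genes, 818 were higher and 1165 lower (limma, Benjamini-Hochberg adjusted p under 0.05), with 55 and 213 of them past 1 on the log2 scale. These counts depended on single libraries. They were 126 higher and 320 lower without CNV replicate 1, 129 and 335 without CNV replicate 2, and 1457 and 1758 without CNV replicate 3. They were 146 and 320 without BetP-Gel@Ran replicate 2 and 182 and 468 without replicate 3, and 363 were higher without replicate 1. They were also 263 and 590 without the filter on low values, and 42 and 42 with the lens list as a covariate, which shared 68 of the 1983 calls. With that covariate Ppbp, Cxcl5, Il1b, Csf3, Cxcl2, Il33, Aqp4, Socs3, Nefl and Nefh kept their calls. The calls of Spp1, Serpina3n, Ltf, Lyz2, Cd14, Thbs1, Timp1, Esm1, Vegfa, S100a8, Flt1, Nrn1, Kcnj10, Hlf, Krt12, Tsc22d3 and Cryaa were lost. For the lens gene Cryaa the loss is no evidence, as the covariate is the mean of the lens list. Lens genes took 0.0171 to 0.0401% of reads in CNV libraries and 0.156 to 2.87% in the other groups. The covariate thus largely follows the CNV grouping and takes up part of any difference of the CNV libraries. The other kept and lost calls therefore do not show which differences follow lens content. List member counts were not recomputed in these settings.

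Ppbp was at 6.15 ± 6.07 FPKM in BetP-Gel@Ran libraries against 1335 ± 567 in CNV libraries, a log2 fold change of -7.76 ± 0.59 (limma adjusted p = 9.78e-04). Cxcl5 was at 2.54 ± 1.31 FPKM (log2 -4.50 ± 0.32, limma adjusted p = 4.33e-04) and Il1b at 1.35 ± 1.23 FPKM (log2 -3.64 ± 0.35, limma adjusted p = 0.00134). Csf3 changed by -3.39 on the log2 scale and Cxcl2, a further neutrophil chemokine gene, by -3.03, at 0.288 ± 0.178 FPKM. Il33 stood at 16.8 ± 1.49 FPKM against 52.6 ± 9.57 in CNV libraries. Cytokine and chemokine genes were lower in 18 of 28 (3 higher and 19 lower adjusted over the list alone), at a median of -1.002 (camera adjusted p = 2.84e-07, and adjusted p = 0.335 with an estimated correlation). Neutrophil markers were lower in 7 of 9, the same count adjusted over the list alone, with Ltf at 23.9 ± 10.3 FPKM (median -1.66, camera adjusted p = 9.43e-06, and adjusted p = 0.335 with an estimated correlation). Red blood cell genes had a median of -0.64, with none called, and were not called as a list (camera adjusted p = 0.0607). Microglia and macrophage markers had a median of -0.63, with 16 of 28 lower and 1 higher (19 and 1 adjusted over the list alone; camera adjusted p = 1.10e-06, and adjusted p = 0.405 with an estimated correlation). Lyz2 was at 569.9 ± 73.7 FPKM, and Cd14, a receptor for bacterial lipopolysaccharide, was at 6.88 ± 1.26 against 20.4 ± 6.25 FPKM. Spp1 changed by -3.60 and Thbs1, an inhibitor of angiogenesis, by -2.04. S100a8 (limma adjusted p = 0.0222) was not called without CNV replicate 1 (adjusted p = 0.0713), CNV replicate 2 (0.0904), BetP-Gel@Ran replicate 1 (0.0572) or BetP-Gel@Ran replicate 2 (0.0691).

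Reactive gliosis and cell stress genes were lower as lists too, whereas Müller glia markers were not called, with 5 of 20 higher and 1 lower, or 6 and 2 adjusted over the list alone (median 0.08, camera adjusted p = 0.391). Aqp4 was at 3.16 ± 0.695 FPKM against 23.4 ± 3.99 in CNV libraries (log2 -2.55 ± 0.15, limma adjusted p = 8.56e-05), and Serpina3n at 63.8 ± 9.55 FPKM (log2 -2.32 ± 0.30, limma adjusted p = 0.00498). Socs3 changed by -1.83 and Timp1, a metalloproteinase inhibitor gene, by -2.08. Gfap and C3 were not called, at 37.4 ± 3.70 and 15.5 ± 2.96 FPKM (limma adjusted p = 0.669 and 0.201). Reactive gliosis genes (median -0.46, camera adjusted p = 1.11e-04) and NF-kappa B and inflammasome genes (median -0.37, camera adjusted p = 5.27e-05) were lower, each with adjusted p = 0.405 with an estimated correlation. Adjusted over the list alone, 13 gliosis and 13 NF-kappa B genes were lower, against 10 and 9 over all genes. The oxidative phosphorylation list shifted to lower values (median -0.16, camera adjusted p = 5.04e-04, and adjusted p = 0.405 with an estimated correlation), with 3 of 37 genes called lower and 2 adjusted over the list alone. Complement genes (median -0.18, camera adjusted p = 0.00394) and apoptosis and cell stress genes (median -0.23, camera adjusted p = 3.08e-05) were lower, each with adjusted p = 0.335 with an estimated correlation. Of these, 7 of 20 and 10 of 28 were called lower, or 8 and 13 adjusted over the list alone. Cell cycle genes were lower in 6 of 24 and in 19 adjusted over the list alone (median -0.55, camera adjusted p = 2.84e-07, and adjusted p = 0.497 with an estimated correlation). The hypoxia and glycolysis list (median -0.29, camera adjusted p = 0.00518) and the pigment epithelium list (median -0.34, camera adjusted p = 0.00728) shifted to lower values, each with adjusted p = 0.562 with an estimated correlation. Hypoxia genes were mixed over 30 gene entries of 29 symbols, with 3 higher and 5 lower, or 3 and 8 adjusted over the list alone. Pigment epithelium markers had 1 of 20 higher and 3 lower, or 1 and 7 adjusted over the list alone. The pigment epithelium call was lost without CNV replicate 3 (adjusted p = 0.0884). Vegfa was at 5.84 ± 0.444 FPKM against 9.98 ± 2.25 (limma adjusted p = 0.0250), a call lost without CNV replicate 1 (adjusted p = 0.0887), CNV replicate 2 (0.0913), or BetP-Gel@Ran replicate 1, 2 or 3 (0.0637, 0.0628 and 0.0744). Esm1 changed by -1.46, while Flt1 was higher, at 1.62 ± 0.113 against 0.772 ± 0.128 FPKM (limma adjusted p = 0.0105).

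Retinal ganglion cell markers were higher than in CNV samples in 8 of 16 (10 adjusted over the list alone), at a median of 0.49 (camera adjusted p = 9.43e-06, and adjusted p = 0.405 with an estimated correlation). The neurofilament genes Nefl and Nefh stood at 30.7 ± 3.43 and 8.55 ± 0.204 FPKM against 12.04 ± 1.26 and 2.601 ± 0.377 in CNV libraries (limma adjusted p = 0.00781 and 0.00498), and Nrn1 at 6.82 ± 0.969 against 2.52 ± 0.813. Kcnj10, a potassium channel gene of Müller glia, was at 6.73 ± 0.947 against 3.04 ± 0.818 FPKM. Rod markers were higher as a list (median 0.30, camera adjusted p = 3.25e-04, and adjusted p = 0.537 with an estimated correlation), with 1 of 24 called (0 adjusted over the list alone). Amacrine cell markers and lens genes (medians 0.45 and 3.33, camera adjusted p = 0.00421 and 8.92e-08) were higher, each with adjusted p = 0.497 with an estimated correlation. Of these, 2 of 9 and 9 of 23 were called higher, or 6 and 17 adjusted over the list alone. The lens gene Cryaa, the alpha A crystallin, was at 505 ± 429 against 9.45 ± 8.01 FPKM (limma adjusted p = 0.0380), and single omissions ended that call, with adjusted p of 0.0945 without CNV replicate 1, 0.134 without CNV replicate 2, 0.0618, 0.114 and 0.0910 without BetP-Gel@Ran replicates 1, 2 and 3, and 0.0509 without untreated replicate 1. Clock genes (median 0.34, camera adjusted p = 3.08e-05, and adjusted p = 0.405 with an estimated correlation) were higher, with 8 of 19 higher and 1 lower, or 12 and 1 adjusted over the list alone. The muscle list shifted to higher values (median 0.36, camera adjusted p = 0.00129, and adjusted p = 0.562 with an estimated correlation), but none of its 15 genes was called, nor when adjusted over the list alone. Hlf, a clock output transcription factor gene, was at 27.7 ± 0.758 against 15.0 ± 3.39 FPKM, and the corneal Krt12 at 3516 ± 44.5 against 1673 ± 496. Glucocorticoid-induced genes were not called as a list (median 0.06, mean -0.04, camera adjusted p = 0.650). Tsc22d3 was higher, at 31.1 ± 5.12 FPKM (limma adjusted p = 0.0137), a call lost without CNV replicate 1 (adjusted p = 0.0532) or BetP-Gel@Ran replicate 2 (0.0534). Oxidative stress genes (camera adjusted p = 0.0357, and adjusted p = 0.497 with an estimated correlation) and immediate early genes (camera adjusted p = 0.0357, and adjusted p = 0.562 with an estimated correlation) shifted to lower values as lists, but omissions ended both calls. Oxidative stress genes had 5 of 31 higher and 7 lower, or 5 and 10 adjusted over the list alone. Immediate early genes had 1 of 19 higher and 5 lower, or 3 and 8 adjusted over the list alone. The oxidative stress call went without CNV replicate 2 (0.0846) or CNV replicate 3 (0.0919), and the immediate early call without untreated replicate 3 (0.0535), CNV replicate 2 (0.0595), CNV replicate 3 (0.0564) or BetP-Gel@Ran replicate 2 (0.0652).

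Against untreated samples, BetP-Gel@Ran samples had higher macrophage, complement and antigen presentation genes and lower rod, muscle and oxidative phosphorylation genes as lists. These list calls were lost with an estimated correlation, with adjusted p = 0.0606 to 0.342 with an estimated correlation. Of 14086 tested genes, 2265 were higher and 2548 lower (limma, Benjamini-Hochberg adjusted p under 0.05), with 150 and 325 past 1 on the log2 scale. The count of higher genes was 1438 without BetP-Gel@Ran replicate 3. Of the called genes, 47.1% were higher, which became 58.8% with reads scaled to each library's own total and 63.0% with FPKM divided by its sum. Macrophage markers were higher in 22 of 28 (23 adjusted over the list alone), at a median of 1.01 (camera adjusted p = 1.60e-11, and adjusted p = 0.277 with an estimated correlation). Mpeg1, a pore-forming protein gene of macrophages, was at 13.1 ± 3.04 against 1.71 ± 0.558 FPKM, Lyz2 at 569.9 ± 73.7 against 222 ± 16.4, and Mrc1, the macrophage mannose receptor gene, at 5.32 ± 0.582 against 2.26 ± 0.147. Complement genes were higher in 14 and lower in 1 of 20, the same counts adjusted over the list alone (median 0.69, camera adjusted p = 6.36e-06, and adjusted p = 0.0606 with an estimated correlation). C3 was at 15.5 ± 2.96 against 2.51 ± 0.829 FPKM (log2 2.25 ± 0.22, limma adjusted p = 1.73e-04), and C4b, a component of the classical pathway, at 12.9 ± 2.44 against 3.98 ± 0.283. The antigen presentation list shifted to higher values by a median of 0.35 (camera adjusted p = 2.80e-04, and adjusted p = 0.277 with an estimated correlation). Of its genes, 8 of 19 were called higher (10 adjusted over the list alone), with the class II gene H2-Aa at 73.2 ± 6.84 against 29.3 ± 2.91 FPKM. Cytokine and chemokine genes had a median of 0.56, with 14 higher and 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 4.97e-04, and adjusted p = 0.348 with an estimated correlation). Ccl8, a monocyte chemokine gene, was at 111 ± 22.9 against 21.5 ± 5.08 FPKM (limma adjusted p = 2.05e-04), while Il1b was not called (limma adjusted p = 0.229) and Cxcl2 changed by -1.31 on the log2 scale. Neutrophil markers were not called as a list (camera adjusted p = 0.274).

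Serpina3n was above the untreated level, at 63.8 ± 9.55 against 7.65 ± 0.602 FPKM (log2 2.90 ± 0.30, limma adjusted p = 2.90e-04), as did Gfap, at 37.4 ± 3.70 against 14.5 ± 1.34 (limma adjusted p = 0.00280). Reactive gliosis genes (median 0.32, camera adjusted p = 3.83e-04, and adjusted p = 0.342 with an estimated correlation), NF-kappa B and inflammasome genes (median 0.24, camera adjusted p = 0.00295, and adjusted p = 0.348 with an estimated correlation) and lymphocyte markers (median 0.59, camera adjusted p = 0.0197, and adjusted p = 0.312 with an estimated correlation) were higher. Called members were 10 of 24 higher for gliosis, 8 of 21 higher and 1 lower for NF-kappa B, and 4 of 8 higher and 1 lower for lymphocytes. Adjusted over the list alone, 11, 10 and 5 were higher. Wfdc17, a gene induced in macrophages, was at 125 ± 11.1 against 22.2 ± 1.89 FPKM, and Saa3, an acute phase gene, at 4.99 ± 0.834 against 0.119 ± 0.0463. Oxidative phosphorylation genes were lower in 33 of 37 (34 adjusted over the list alone), at a median of -0.55 (camera adjusted p = 4.21e-15, and adjusted p = 0.0778 with an estimated correlation), with the cytochrome c1 gene Cyc1 at 56.5 ± 1.27 against 99.9 ± 4.602 FPKM. All 15 muscle genes were lower, also when adjusted over the list alone (median -2.26, camera adjusted p = 7.92e-14, and adjusted p = 0.277 with an estimated correlation). Rod markers were lower in 19 of 24 (19 adjusted over the list alone), with Nr2e3 at 24.2 ± 2.99 against 59.0 ± 4.02 FPKM (median -0.87, camera adjusted p = 5.16e-08, and adjusted p = 0.342 with an estimated correlation). Retinal ganglion cell markers were lower in 12 of 16 (13 adjusted over the list alone), by a median of -0.75 (camera adjusted p = 2.30e-05, and adjusted p = 0.348 with an estimated correlation). Glucocorticoid-induced genes were lower in 14 and higher in 2 of 24, or 14 and 3 adjusted over the list alone (median -0.58, camera adjusted p = 3.05e-04, and adjusted p = 0.0778 with an estimated correlation), with Pdk4, a kinase gene that limits pyruvate oxidation, at 0.827 ± 0.181 against 15.3 ± 2.25 FPKM and Fkbp5 at 7.37 ± 2.18 against 14.8 ± 0.966. Hypoxia and glycolysis genes were lower, with 13 of the 30 entries lower and 2 higher, the same counts adjusted over the list alone (median -0.31, camera adjusted p = 0.00353, and adjusted p = 0.678 with an estimated correlation). Horizontal cell markers, of which 3 were tested, were lower (camera adjusted p = 0.0248, and adjusted p = 0.277 with an estimated correlation), a call lost without the filter on low values (adjusted p = 0.105). Lens genes were not called as a list (median 0.22, mean -0.71, camera adjusted p = 0.527), although Cryge was at 0.0511 ± 0.0885 against 574 ± 692 FPKM. Vegfa was at 5.84 ± 0.444 against 6.13 ± 0.825 FPKM and was not called (limma adjusted p = 0.810), and Flt1 was higher (limma adjusted p = 0.00433).

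The direction of each CNV change was set beside the difference of BetP-Gel@Ran from CNV samples, without knowing whether the BetP-Gel@Ran mice had CNV. Of the 3166 genes higher in CNV than in untreated samples, 911 (28.8%) were called lower in BetP-Gel@Ran than in CNV samples, and 1625 were called higher than in untreated samples. Ppbp, Il1b, Csf3, Cxcl5 and Aqp4 were among the 911. Of the 3115 genes lower in CNV samples, 533 (17.1%) were called higher in BetP-Gel@Ran than in CNV samples, Nefl and Krt12 among them, and 1957 were called lower than in untreated samples. Of the 1983 genes called between BetP-Gel@Ran and CNV samples, 1444 went against their CNV change, 39 had the direction of their CNV change and 500 had no called CNV change. The 911, 533 and 1444 depended on single libraries, at 287, 104 and 391 without CNV replicate 1, 306, 103 and 409 without CNV replicate 2, and 1351, 908 and 2259 without CNV replicate 3. They were 631, 274 and 905 without BetP-Gel@Ran replicate 1, 296, 112 and 408 without replicate 2, and 431, 143 and 574 without replicate 3. Both comparisons share the CNV libraries, so these counts are not those of independent calls. Over all genes called in CNV against untreated samples, the fold change in BetP-Gel@Ran against CNV had the opposite sign for 79.8% (95% interval 78.8 to 80.8, counting error only). In 20 simulations without any effect, as many genes were taken by largest statistic, and 76.6% had the opposite sign. Those genes were picked for shared noise alone, whereas the real ones also carried differences between CNV and untreated samples. The 76.6% is therefore no estimate of what the shared libraries give in these data. The correlation across genes was -0.69 against -0.50 in the simulations, and the covariance -0.178 against -0.0124. The simulations held no trait shared by the CNV libraries, such as tissue makeup. Any such trait enters both comparisons with opposite signs, so these gaps are no measure of reversal. The sign in BetP-Gel@Ran against untreated was that of the CNV change for 93.7% of the genes, against 76.9% in the simulations. The limit given for the 76.6% holds here too. The share of 79.8% became 81.5 without untreated replicate 3, 84.3 without CNV replicate 3, and 77.7, 78.7 and 81.8 without BetP-Gel@Ran replicates 1, 2 and 3.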

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

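The voom, own-total, FPKM-sum and lens-covariate settings were chosen only after the result was seen, while the other settings were written down earlier. In CNV against untreated, 3166 genes were higher and 3115 lower, and leaving out 1 library gave 2593 to 3127 and 2513 to 3075. The higher count was 1735 with a filter of 5 FPKM. In BetP-Gel@Ran against CNV, 818 were higher and 1165 lower. Leaving out 1 library gave 126 to 1457 higher and 320 to 1758 lower, lowest without CNV replicate 1 and highest without CNV replicate 3. The counts were 263 and 590 without a filter, 537 and 652 with only the 2 groups in the fit, and 1518 and 1844 with array weights, which gave the lowest weight to CNV replicate 3 (0.517). The cause of this dependence was not tested. In BetP-Gel@Ran against untreated, 2265 were higher and 2548 lower, with 1438 to 2482 and 1760 to 2647 on leaving out 1 library. The higher count was 1337 with a filter of 5 FPKM, and the lower count was 1555 with FPKM divided by its sum.

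With the replicate number as a block, 523 genes were higher in BetP-Gel@Ran than in CNV samples, and 6048, 1398 and 4467 genes were called in the 3 comparisons. Libraries with the same number correlated at -0.148 to 0.0841 after removal of group means, and libraries with different numbers at -0.191 to 0.171. Of 9 libraries, 2 correlated best with one of their own number, so the numbers do not pair the libraries. Median-of-ratios scaling was void, since the deposited values already carried it.

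Lists called were 18, 19 and 14 in the 3 comparisons, and 18 to 20, 17 to 21 and 14 to 17 on leaving out 1 library. They were 1, 0 and 0 with camera at an estimated correlation, and fry gave 11 in BetP-Gel@Ran against CNV. The opposite-sign share of 79.8% was 77.7 to 84.3 on leaving out 1 library, 82.7 without a filter, 77.8 with a filter of 5 FPKM, 81.0 with FPKM divided by its sum and 91.8 with the lens covariate.

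With the lens covariate, CNV against untreated gave 1126 higher and 1610 lower genes, and BetP-Gel@Ran against CNV gave 42 and 42. In BetP-Gel@Ran against untreated it gave 2164 and 2559. The lens list was lowest in every CNV library, so the covariate overlaps with the CNV grouping and takes up part of any CNV difference. Fewer calls in the comparisons with CNV therefore do not show that lens content caused the lost ones. Across the comparisons 138 results of named genes lost their call with the covariate. Since the covariate is the mean of the lens list itself, it removes that list's mean change by construction. Changes of the lens list and of crystallin genes under it are therefore not evidence about them. The covariate reversed the sign of Crygs (1.14, limma adjusted p = 0.432) and Cryba1 (1.85, limma adjusted p = 0.0885) in CNV against untreated. The lens list reversed to a median of 1.14 in CNV against untreated (camera adjusted p = 0.373). In BetP-Gel@Ran against CNV its median shrank from 3.33 to 0.0545, and the direction of its test reversed without a call (camera adjusted p = 0.845). The cone list reversed to -0.47 in BetP-Gel@Ran against CNV (camera adjusted p = 0.00165). At 16990118 to 18753737 reads per library, the reads behind a gene near 1 FPKM depended on its length. In untreated replicate 1, Igkc at 0.886 FPKM had 8 reads and Kdm5d at 1.12 FPKM had 288. Fold changes of such low genes are understated.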

Other observations

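All tests of this part other than the splits of libraries were chosen only after the result was seen. Splitting the 6 libraries of a comparison in all 10 ways gave 1 split with as many genes called as the real grouping in each comparison, which was the real grouping itself. The real groupings called 6281, 1983 and 4813 genes, and the highest other split 0, 3 and 0. For gene lists, 5, 1 and 7 of the 10 splits called as many lists as the real 18, 19 and 14, with up to 21, 18 and 20 in another split. With 10 splits these are too few for a share under 0.05. Every other split mixes the groups, which adds their difference to the spread, so few called genes are expected there.

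Transcripts of cornea, lens and skeletal muscle were present in every library, although the labels name choroidal and retinal flat mounts. The lowest median of the cornea list in any library was 301 FPKM, which is consistent with cells of neighbouring eye tissues in the dissected samples. The tables argue against libraries without retina, as the lowest median of the rod list in any library was 58.0 FPKM. Part of the lens, cornea and muscle differences between groups may therefore follow dissection, and how much stays open. These libraries do not show which tissue a transcript came from. Differences of other genes, such as Glul, Pdk4 and the oxidative phosphorylation list, may also follow tissue makeup, which was not tested. Cornea genes moved both ways in CNV against untreated, with 2 of 14 higher and 6 lower, also when adjusted over the list alone. Krt12 was at 1383 to 2246 FPKM in CNV and 4319 to 5313.5 in untreated libraries. Krt14 was at 553 to 2252 and 282 to 316 FPKM in the same order. A uniformly different share of cornea alone would not move genes both ways.

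Rod, ganglion cell and muscle transcripts were lower in CNV than in untreated libraries, and 15 of 15 muscle genes were called lower, consistent with less extraocular muscle in the dissected samples, though a regulated fall would look the same. A uniformly smaller share of whole retina would have lowered all retinal lists alike, but the median log2 ratio of rod markers minus that of bipolar cell markers was -1.22 (95% interval -1.54 to -0.65). Such intervals come from resampling the marker genes, which are not independent, and leave out the spread between libraries. Only 10 of 18 bipolar cell markers were tested, and their list took 0.0332% of untreated reads against 2.28% for rods. Whether such low markers came from retina alone is not known, so the difference does not exclude a smaller share of retina. Rod markers had a median of -1.12 without pseudocount, cone markers -0.77, bipolar markers 0.10, amacrine markers -0.16, ganglion cell markers -2.29, Müller glia markers -0.08 and pigment epithelium markers 0.20. The interval of the difference from rods held 0 for amacrine markers (-1.19 to 1.14) and ganglion cell markers (-0.13 to 1.59), but not for cone markers (-1.35 to -0.10). It stays open whether rods and ganglion cells were lost or lowered these transcripts, or whether the samples held less retina. Uneven dissection of parts of the retina was not tested.

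Some genes set the untreated libraries apart from the other 6. By a rule of at least 3-fold set after a first look at the values, 112 genes did so (83 higher and 29 lower), against 47 for the CNV and 1 for the BetP-Gel@Ran libraries, the latter being Cxcl2. Examples are Wdfy1 at 1.25, 5.78 and 5.20 FPKM, Pglyrp4 at 15.2, 0.749 and 0.557, and Tpm3-rs7 at 16.2, 104 and 104. For Rps3a2, the summed reads of both copies changed by -0.14 in CNV and -0.0594 in BetP-Gel@Ran libraries relative to the median of ribosomal protein genes, which indicates that reads of Rps3a1 were counted on Rps3a2. Many of the 83 are skeletal muscle genes, and they also include Cryga, Cryge, Crygf, Ifnl2, Ifnl3 and mt-Tg, at or near 0 in the other 6 libraries. Treatment and any strain, batch or sampling time difference between the untreated mice and the other 6 run together. These causes therefore cannot be told apart for the 112 genes other than Rps3a2, nor for the other genes called against untreated samples. For Rps3a2 the reads point to counting on another copy rather than to a change of expression. Why its reads were counted differently in the untreated libraries was not tested.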
